A study of Mus musculus with 12 samples.

How the data were processed

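Gene expression was measured by RNA sequencing of poly(A)-enriched libraries from CD4+CD25+ Treg and CD4+ Tconv sorted by flow cytometry from mouse spleen, per the labels' protocols. Groups were taken from the sample titles: 6 groups of 2 libraries, for 12 libraries in all. The titles also carry a tag, L3, L4 or L5, whose meaning is not stated. Only aged Treg 2 and aged Tconv 2 carry L3.

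The authors deposited estimated counts per gene, quantified with Salmon 0.9.1 per the labels and summed to genes with tximport per the file headers and name; the genome build is mm10 per the labels and the transcript annotation is not stated. The authors also deposited log2 values scaled with DESeq2, per the labels, whose exact transform is not stated; they match log2 of the counts for highly counted genes and are shrunken for low ones. They had been planned to be log-transformed with 1 added and were used directly instead, as they already lie on a log scale. The estimated count table holds 13404 rows, of which 11486 have a count in at least 1 library and 18 carry a name that a spreadsheet turned into a date; 23.5% of its values are whole. The log2 table holds 11271 rows. In GENCODE M21 13134 symbols were found. Dcaf1 is named Vprbp in both tables. Genes that the tables do not hold were not analysed here.

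The estimated counts were rounded to whole numbers and tested in R 4.3.3 with the edgeR 4.0.16 quasi-likelihood test. Library scaling was by TMM, low-count genes were removed with filterByExpr (9495 genes tested, 1991 removed), and 1 fit over all 12 libraries held 6 group means with 6 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg within each of 8 comparisons, with a threshold of 0.05. Standard errors come from the fitted dispersion, and CPM values use TMM-scaled library sizes, with a prior count of 2 for log2 CPM. Of 33 gene lists fixed before the data were examined, 31 had at least 5 tested members and were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01. Alternatives were an estimated correlation and fry, which asks whether a list's genes move on balance one way and does not compare them with other genes. Lists of 17 T cell genes and 10 pancreatic genes were written after the data were seen.

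The comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. The rule names, in each comparison of 2 groups, the 8 largest increases and 8 largest decreases among called genes with a mean of at least 4 CPM and groups that do not overlap, leaving out immunoglobulin and T cell receptor segments and unnamed genes. It adds up to 4 called members per gene list with the smallest adjusted p, and always Dcaf1, Foxp3, Il2ra, Cdkn1a, Cdkn2a and Gstp1 in Treg. Where edgeR called 0 genes, the same rule was applied to DESeq2, a step added after the values were seen. The overlap of the age and label effects was set beside 50 simulated draws of unchanged groups, in which the young libraries were drawn anew around their mean. Genes near Dcaf1 used RefSeq positions on GRCm38, the build of mm10; other coordinates are from GENCODE M21.

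Alternatives fixed beforehand were RLE size factors, no low-count filter, DESeq2 1.42.0 (Wald test), fits of the 6 libraries of a cell type or of the young groups alone, a replicate block, a term for the tag, limma-trend on the deposited log2 values, leaving out each library in turn, and a log2 fold change of at least 1. A sex term, terms for macrophage and B cell transcripts, and leaving out young Treg 2 and aged Treg 1 were added after the data were seen. Each test was tested on simulated data in which 200 genes were changed by log2 sizes of 1 to 4. Totals of 18358477 to 26852448 estimated counts per library make 3 counts over a group equal to 0.0574 to 0.0768 CPM. With groups of 2, neither an outlier test within groups nor a test over other splits of the samples was run.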

Results

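RNA sequencing measured gene expression in regulatory T cells (Treg, the CD4 T cells that restrain immune responses) and conventional CD4 T cells (Tconv) sorted from mouse spleen. The 12 libraries fell into 6 groups of 2: young wild-type mice of 2 months, aged wild-type mice of over 18 months, and mice of 2 months labelled Dcaf1-deficient, each as Treg and as Tconv. Total estimated counts ranged from 18358477 in aged Tconv 1 to 26852448 in the library labelled Dcaf1-deficient Treg 1. For replicates 1 and 2, the totals were 21947127 and 22300535 in young Treg, 24546294 and 22122050 in aged Treg and 26852448 and 22869637 in Treg labelled Dcaf1-deficient. In Tconv they were 22617023 and 18937218 in the young, 18358477 and 21564602 in the aged and 20660563 and 20861562 in the libraries labelled Dcaf1-deficient. Levels below are CPM, counts scaled to library size, with the SD over 2 libraries.

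The targeted gene, Dcaf1 (named Vprbp in the table; mm10 chromosome 9, 106821874 to 106880992), encodes the substrate receptor of a CUL4-DDB1 ubiquitin ligase. Its level was 136 ± 11.5 CPM in young Treg, 116 ± 15.9 in aged Treg and 102 ± 0.741 in Treg labelled Dcaf1-deficient. In Tconv it was 145 ± 2.32 CPM in the young, 104 ± 18.5 in the aged and 132 ± 0.00731 in the libraries labelled Dcaf1-deficient. The log2 fold change of the labelled libraries was -0.42 in Treg (SE 0.14, edgeR adjusted p 0.148) and -0.14 in Tconv (SE 0.14, edgeR adjusted p 0.731). A count over the whole gene does not show whether an exon was deleted, so these libraries are called labelled Dcaf1-deficient throughout.

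**Figure D1:**
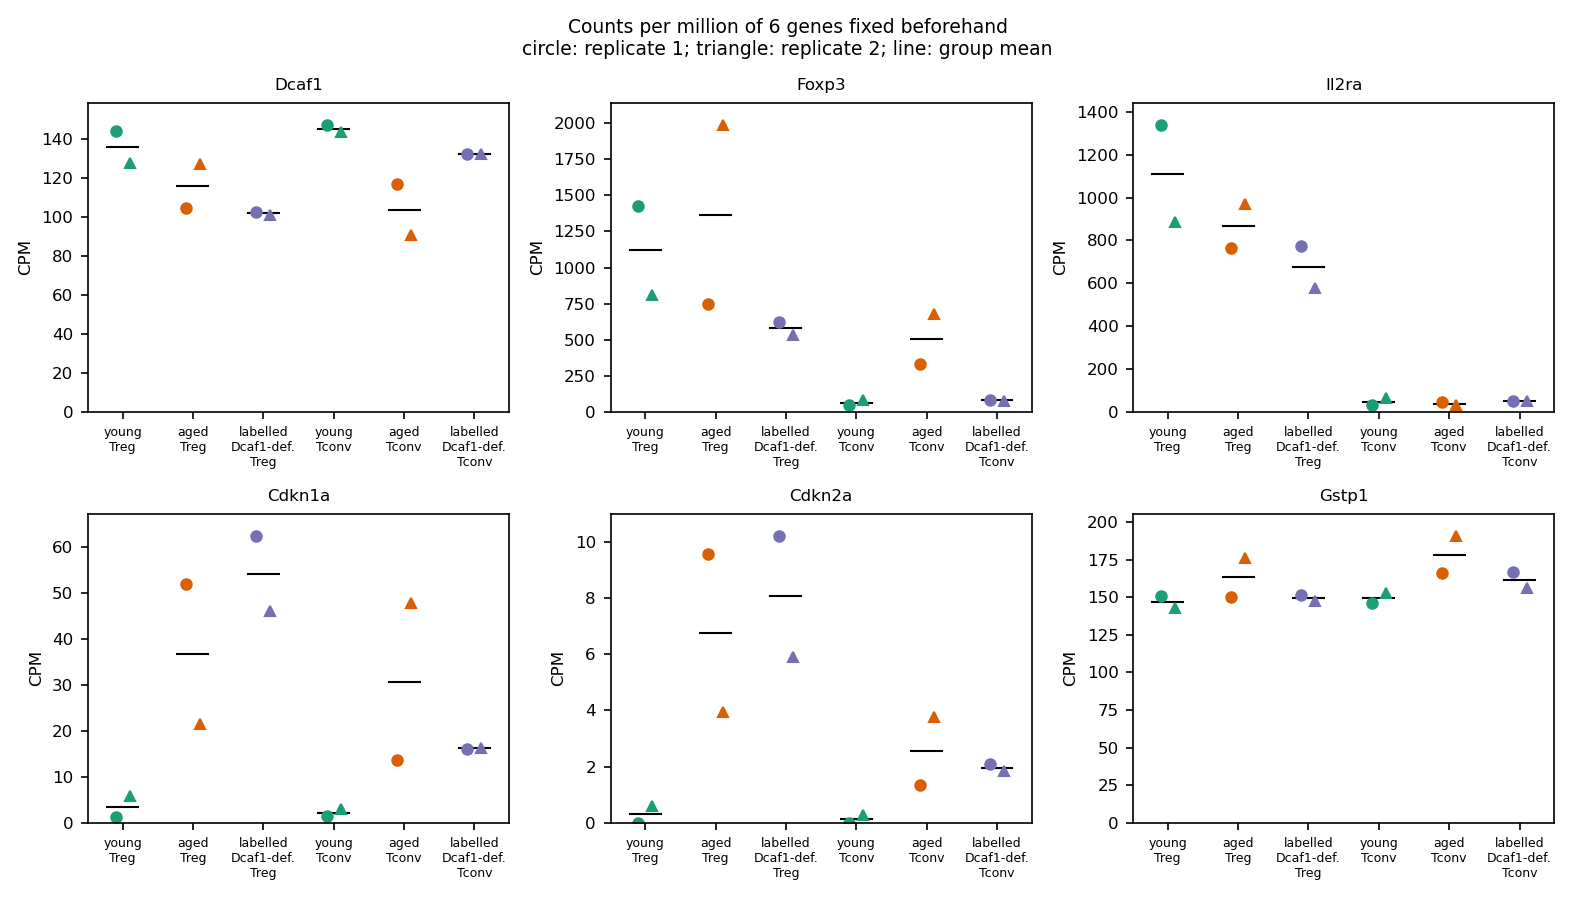
CPM (vertical axes, from 0) of 6 genes fixed beforehand, in the 6 groups; circles are replicate 1, triangles replicate 2 and lines group means. Dcaf1 lies between 90.5 and 147 CPM in all 12 libraries, while Cdkn1a is at 5.71 CPM or below in the 4 young wild-type libraries and at 13.7 CPM or above in the other 8.

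The Treg libraries differed in transcripts of other blood cells. C1qa, a complement gene of macrophages, was at 9.79 CPM in young Treg 1 and 239 in young Treg 2, at 567 in aged Treg 1 and 96.2 in aged Treg 2, and at 694 and 756 in the labelled libraries. Cd79a, a part of the B cell receptor, was at 14.8 and 680 CPM in young Treg, 497 and 12.9 in aged Treg, and 607 and 653 in the labelled libraries. The haemoglobin gene Hbb-bs was at 7.49 and 690 CPM in young Treg, 1617 and 54.5 in aged Treg, and 1928 and 4122 in the labelled libraries; near-identical globin copies make this gene's own share uncertain. At these genes the replicates of young and of aged Treg thus differed widely, while C1qa and Cd79a lay close together in the labelled libraries. Every Treg comparison below includes young or aged Treg and carries that spread. Comparisons within Tconv are not free of it either, since 1 fit over all 12 libraries estimated the spread.

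**Figure D2:**
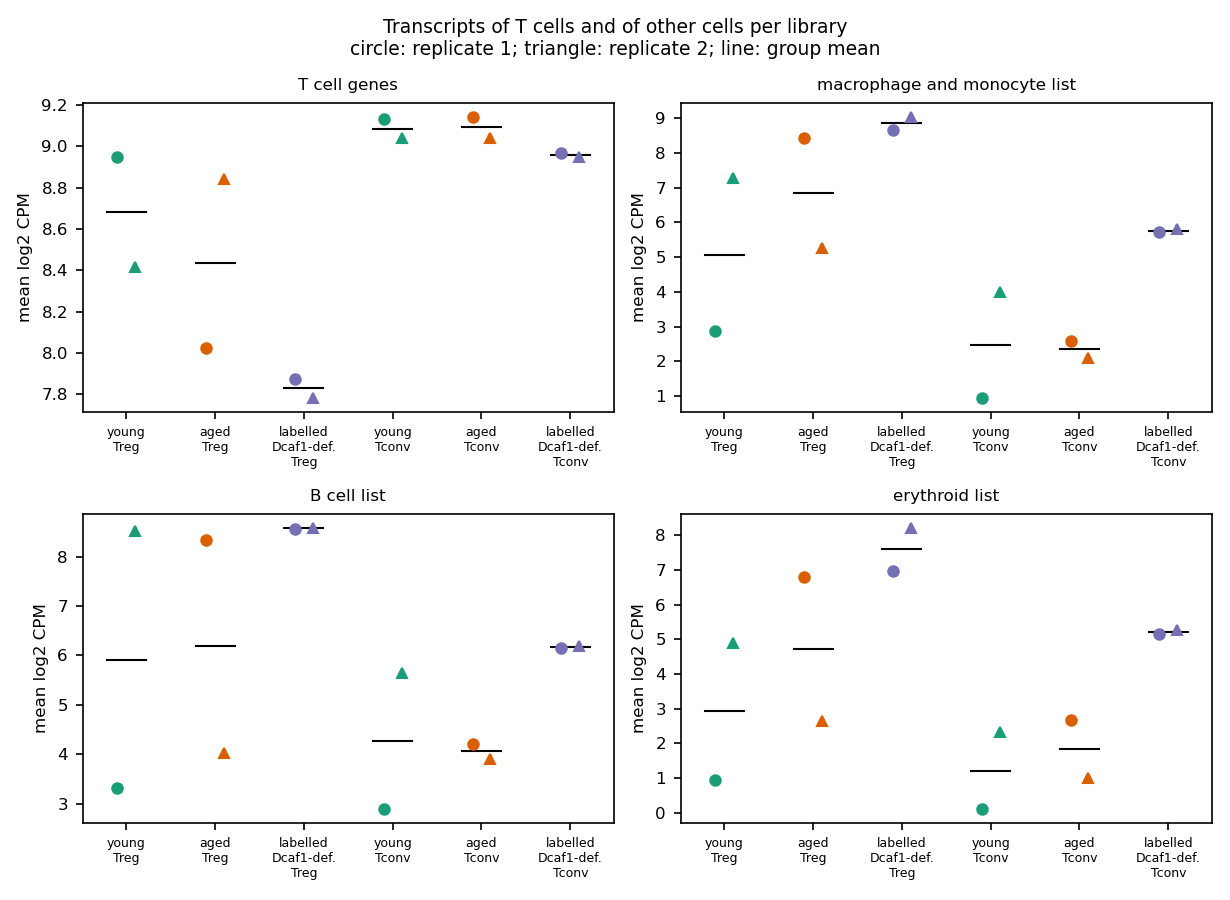
Mean log2 CPM (vertical axes) of T cell, macrophage and monocyte, B cell and erythroid genes in each library; circles are replicate 1, triangles replicate 2 and lines group means. The macrophage list is at 2.87 in young Treg 1 and 7.27 in young Treg 2, and at 8.43 in aged Treg 1 and 5.27 in aged Treg 2.

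Young Treg were compared with young Tconv to show what sets the sorted cell types apart. Foxp3, the transcription factor that defines Treg (chromosome X, 7573644 to 7595245), was at 1120 ± 436 CPM in Treg and 63.0 ± 21.7 in Tconv (log2 fold change 4.15, SE 0.59, edgeR adjusted p 0.0304). Il2ra, which encodes the sorting marker CD25, was at 1112 ± 319 against 47.5 ± 22.2 CPM (4.55, SE 0.41, edgeR adjusted p 0.00602). Ikzf2, the Treg transcription factor Helios, and Socs2, a cytokine signalling inhibitor, were higher by 3.28 and 2.90 on the log2 scale. Cd40lg, the helper ligand of B cells, fell by 2.45 (SE 0.20, edgeR adjusted p 0.00602), and the T cell signalling gene Themis fell by 2.01. The interferon-induced GTPases Gbp3 and Gbp5 were higher by 2.82 and 1.93, though members of this family share sequence and their counts are uncertain. The NADPH oxidase subunit gene Ncf4 rose by 0.96 and the peroxiredoxin gene Prdx6 fell by 0.71.

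Other genes with large differences were higher in Treg for Dnah7a (5.79), Stra6 (4.76), Gbp2b (4.69), Bcam (3.90) and Tnfrsf8 (3.81), and lower for Ntrk3 (-3.60), Il1rl2 (-3.43), Pde3b (-3.14), Tmie (-2.93), Tgfbr3 (-2.84) and Sema4f (-1.92), all log2 fold changes. Cd200, an inhibitory ligand, rose by 1.54. In all, edgeR called 47 genes higher and 29 lower of 9495 tested; leaving out either young Tconv library left 0 calls, leaving out young Treg 1 left 6 and young Treg 2 left 21, and the fit of the young groups alone left 2. Terms for macrophage and B cell transcripts left 1. Of the 15 Treg identity genes, 5 were called over all genes and 15 adjusted over the list alone (median log2 fold change 3.06; camera adjusted p 9.34e-18, or 0.153 with an estimated correlation). NADPH oxidase genes, which phagocytes and B cells also express, had 1 and 2 of 7 (1.25; 0.00313, 0.153). Their mean log2 CPM was 3.91 and 5.08 in young Treg and 2.88 and 3.48 in young Tconv, and the macrophage list was higher in Treg too (2.87 and 7.27 against 0.95 and 4.003). In all 6 lists were higher and 2 lower by camera, and none with an estimated correlation.

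Aged Tconv were compared with young Tconv to ask what age changed in conventional cells. Transcripts of inhibited and cytotoxic CD4 T cells rose: Eomes, a T-box factor, from 16.1 ± 0.295 to 322 ± 174 CPM (log2 fold change 4.32, SE 0.43, edgeR adjusted p 0.0123), and Pdcd1, the receptor PD-1, from 22.4 ± 3.18 to 956 ± 874 CPM (5.41, SE 0.91, edgeR adjusted p 0.0208). The granzyme gene Gzmk rose by 7.30 and Tox2, a nuclear factor of exhausted and follicular cells, by 4.47. Genes usual in Treg also rose: Foxp3 from 63.0 ± 21.7 to 505 ± 241 CPM (3.002, SE 0.56, edgeR adjusted p 0.0248), Ikzf2 by 2.85, the costimulatory receptor Tnfrsf4 by 3.58 and the cytokine Il10 by 5.33. Il2ra stood at 31.8 and 63.2 CPM in young and 43.1 and 29.7 in aged Tconv. Lef1 and Foxo1, transcription factors of naive T cells, fell by 2.14 and 1.24 (edgeR adjusted p 0.0323 and 0.0348).

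Among effector genes, Maf rose by 3.21, Nfil3 by 3.54, Areg (a growth factor) by 5.17, and the helper cytokines and their regulators Il21 by 4.03, Bcl6 by 2.18, Il4 by 3.19 and Tnf by 0.78. Of genes tied to senescence, the cell cycle inhibitors Cdkn1a and Cdkn2c rose by 3.83 and 2.37 and the deacetylase Sirt1 fell by 0.65. The secreted factors Cxcl10, Ccl5 and Spp1 rose by 3.77, 5.24 and 7.42, and the p53 targets Phlda3 and Ei24 by 2.77 and 0.90, while Sesn1 fell by 1.52. In redox metabolism, sulfiredoxin Srxn1 rose by 4.71 and Prdx2 by 0.52, while Prdx6 and Txnip (a thioredoxin inhibitor) fell by 0.62 and 1.62. The glutathione S-transferases Gstt3 and Gstt1 rose by 4.25 and 4.23, and the NADPH oxidase genes Ncf4 and Noxa1 by 0.86 and 4.12.

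The glycolytic genes Gapdh, Tpi1, Slc16a3 (a lactate carrier) and Aldoa rose by 1.20, 2.95, 4.49 and 1.27. Ribosomal protein genes fell, 37 of 62 being called and 56 adjusted over the list alone, with Rpl35a at -0.86, Rpl22 at -0.61, Rpl13 at -0.68 and Rpl39 at -0.67; processed pseudogene copies make single members uncertain. Interferon genes went both ways: Gbp3, Gbp5 and Oas1a rose by 1.86, 1.56 and 1.26, while Ifit2 and Oas2 fell by 1.18 and 2.67. The replication genes Mcm6 and Tk1 rose by 1.36 and 1.69, Nr4a2 (an immediate early receptor) by 3.15, Hspa5 (a chaperone) by 0.96 and the sterol gene Ebp by 0.59. The phosphatase gene Dusp2 fell by 1.33 and the integrin gene Itgb3 by 2.08, and the collagen gene Col1a1 rose by 5.25.

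The protease gene Ctse fell from 619 ± 3.22 to 77.8 ± 37.0 CPM (log2 fold change -2.99, SE 0.33, edgeR adjusted p 0.0126). Rapgef4, Tet1, Chdh and Galnt10 fell by 2.60, 2.35, 2.31 and 2.03. Genes nearly absent from young Tconv made up the largest increases. Col16a1 was at 19.7 and 561 CPM in the aged libraries, Cxcl3 at 3.55 and 204, Irg1 at 2.06 and 147, Krt17 at 11.4 and 162, Wipf3 at 3.50 and 87.0, and Ecel1 at 62.7 and 63.8; each averaged at most 0.102 CPM in the young. Vangl1 (1.11 and 39.1 CPM) and Clgn (3.11 and 15.2 CPM) had 0 counts in young Tconv, which allows up to 0.0760 CPM over the group, so their group means were at least 264-fold and 120-fold higher. Such limits cover counting error only, and aged Tconv 2 held most of these transcripts except Ecel1.

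**Figure D3:**
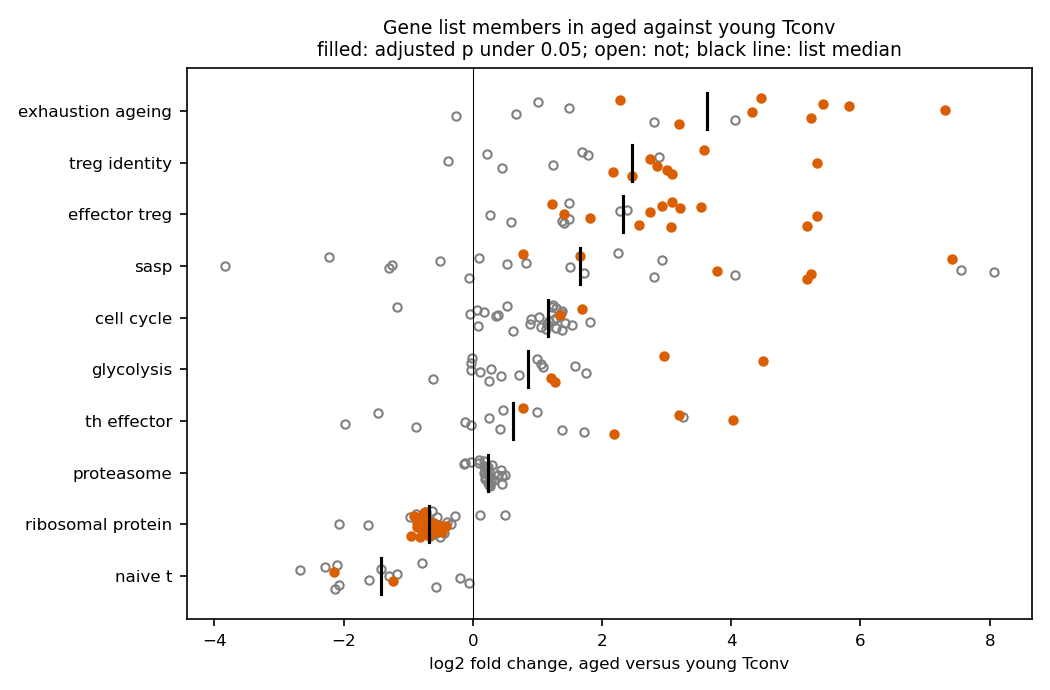
Log2 fold changes between aged and young Tconv (horizontal axis) of the members of biological gene lists that passed the camera threshold; filled points have an edgeR adjusted p under 0.05, open points do not, and black lines are list medians. The exhaustion list has its median at 3.63 and the ribosomal list at -0.68.

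In all, edgeR called 606 genes higher and 235 lower with age in Tconv, against 2043 calls by DESeq2 and 918 by limma. The count rested on few libraries: it was 0 without either young Tconv library, 93 without aged Tconv 2 and 2340 without aged Tconv 1. It was 303 with a sex term and 437 with a term for the tag of the titles, and only aged Tconv 2 of these 4 libraries read as female (Xist at 1263 CPM). It was also the only one of them with the tag L3. Age, sex and tag therefore cannot be told apart for increases that rest on aged Tconv 2. Of the lists, 8 were higher and 2 lower by camera, and none passed with an estimated correlation. Members called over all genes and adjusted over the list alone were 8 and 12 of 15 for Treg identity (camera adjusted p 8.35e-06, estimated correlation 0.417) and 12 and 17 of 20 for effector Treg (8.07e-09, 0.417). They were 8 and 11 of 14 for exhaustion (3.17e-08, 0.417), 4 and 7 of 16 for helper effector genes (0.0415, 0.417), 6 and 10 of 23 for secreted senescence factors (0.0133, 0.705) and 4 and 9 of 18 for glycolysis (0.00106, 0.633). Naive genes had 2 and 3 of 15 (8.35e-06, 0.633), cell cycle genes 2 and 2 of 30 (0.0251, 0.871), and proteasome genes 0 and 0 of 29, with 26 higher (0.00106, 0.804). The cell cycle list averaged 3.38 and 4.07 log2 CPM in young Tconv and 3.70 and 5.23 in aged Tconv, so its rise came from aged Tconv 2. Ribosomal genes reached 4.04e-25, or 0.417 with an estimated correlation.

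Aged Treg were compared with young Treg to ask what age changed in regulatory cells. Cdkn1a, the inhibitor p21, was at 1.27 and 5.71 CPM in young and 51.9 and 21.4 in aged Treg (log2 fold change 3.39, SE 0.87, edgeR adjusted p 0.154). Cdkn2a, which encodes p16 and p19, was at 0 and 0.606 CPM in young and 9.58 and 3.96 in aged Treg (edgeR adjusted p 0.197). The higher aged values of both genes came from aged Treg 1, whose label is doubted in the closing section. Without that library both rises rest on aged Treg 2 alone. Foxp3 was at 1120 ± 436 CPM in young and 1366 ± 877 in aged Treg (0.29, SE 0.52, edgeR adjusted p 0.796), and its direction turned without young Treg 2 or aged Treg 2. Il2ra changed by -0.36 (SE 0.35) and the glutathione S-transferase gene Gstp1 by 0.15 (SE 0.11), with edgeR adjusted p of 0.615 and 0.461.

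No gene passed in edgeR, with 0 higher and 0 lower; 1697 had an unadjusted p under 0.05, where chance gives 475, and DESeq2 called 427 higher and 295 lower and limma 1 and 1. Without aged Treg 1 edgeR called 434. In simulated data edgeR recovered 6 of 50 genes changed by a log2 size of 1 and 26 of 50 at size 2, calling 1 unchanged gene, while DESeq2 recovered 15 and 36 and called 65 unchanged genes. The largest changes by DESeq2, chosen after the values were seen, were Ctse at 468 ± 16.4 CPM in young and 57.4 ± 3.32 in aged Treg (log2 fold change -3.003, DESeq2 adjusted p 4.15e-16), and increases of Ecel1 (8.19), Nwd2 (7.99), Rasgrf1 (7.80), Col16a1 (6.19), Myh3 (5.99), Cobl (5.51) and Stab1 (5.36), all but Stab1 below 1 CPM in young Treg. Most of these rested on aged Treg 2, as for Nwd2 (1.36 and 21.5 CPM), Rasgrf1 (3.94 and 36.8), Col16a1 (5.64 and 74.7), Myh3 (3.22 and 36.7) and Stab1 (21.01 and 185). Xist, expressed from the inactive X of females, rose by 9.31 through aged Treg 2 alone. Among young and aged Treg this library alone carried the tag L3. Age, sex and tag therefore cannot be told apart for increases that rest on it. Decreases were Ly6c1 (-3.11, with a near-identical neighbour), Gabrr2 (-2.90), Tdrp (-2.90), Selp (-2.73), Arhgap20 (-2.53), St8sia1 (-2.44) and Plagl1 (-2.34).

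Effector Treg genes had 0 of 20 members called over all genes and 17 adjusted over the list alone, with all 20 higher and a median log2 fold change of 1.79 (camera adjusted p 3.48e-13, or 0.371 with an estimated correlation). Naive genes had 0 and 4 of 15 (median -1.22; 2.14e-06, 0.683), cell cycle genes 0 and 0 of 30, all 30 higher (1.18; 2.14e-06, 0.683), and ribosomal genes 0 and 57 of 62 lower (-0.69; 3.71e-29, 0.549). The cell cycle list averaged 4.05 and 4.89 log2 CPM in young Treg and 6.25 and 4.75 in aged Treg, so its rise came from aged Treg 1, whose label is doubted in the closing section. The erythroid list was also higher in aged Treg 1 (6.79 log2 CPM) than in aged Treg 2 (2.64), so RNA of other cells cannot be separated from that rise. Exhaustion genes had 0 and 6 of 14 higher (1.68; 0.0166, 0.683), helper effector genes 0 and 4 of 16 (1.31; 0.00193, 0.284) and secreted senescence factors 0 and 2 of 23 (1.03; 0.00193, 0.683). Antioxidant genes had 0 and 2 of 28 (0.32; 0.00674, 0.683) and interferon genes 0 and 2 of 30 (0.48; 1.84e-04, 0.683). The antioxidant list averaged 5.66 and 6.10 log2 CPM in young Treg and 6.56 and 6.16 in aged Treg, so most of its rise came from aged Treg 1. The senescence list, with 0 and 2 of 11, had a median of -0.08 and a mean of 0.80 and did not pass (camera adjusted p 0.525). In all 10 lists were higher and 2 lower by camera, and none with an estimated correlation; the macrophage list (1.37; 0.00653, 0.683) and the neutrophil list (2.63; 0.0363, 0.683) were among them.

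Treg labelled Dcaf1-deficient were compared with young Treg to ask what loss of Dcaf1 changed at 2 months. Cdkn1a was at 62.3 and 46.0 CPM in the labelled libraries (log2 fold change 3.95, SE 0.89, edgeR adjusted p 0.131), and Cdkn2a at 10.2 and 5.92 CPM (edgeR adjusted p 0.144). Foxp3 was at 580 ± 63.7 CPM (-0.95, SE 0.52, edgeR adjusted p 0.273) and Il2ra at 675 ± 140 (-0.72, SE 0.35, edgeR adjusted p 0.239). T cell genes as a whole fell by a similar amount, from a mean log2 CPM of 8.95 and 8.42 in young Treg to 7.87 and 7.78, so these falls cannot be read as specific to Treg genes. Gstp1 was at 149 ± 2.86 against 147 ± 5.88 CPM (0.02, SE 0.11, edgeR adjusted p 0.889), and its direction turned without young Treg 2. Rpl29, a ribosomal protein gene, was at 34.0 and 31.5 CPM against 744 and 717 in young Treg (DESeq2 log2 fold change -4.43, DESeq2 adjusted p 3.26e-13); its pseudogene copies make the count uncertain.

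No gene passed in edgeR, with 0 higher and 0 lower; 2359 had an unadjusted p under 0.05, DESeq2 called 589 higher and 596 lower, and limma 0 and 0. Without young Treg 2 edgeR called 15. Simulated changes of log2 size 1 were recovered for 7 of 50 genes by edgeR and 18 by DESeq2, and of size 2 for 34 and 39. Increases named by DESeq2 after the values were seen were Col6a4 (7.08), Apol11b (6.21), the erythroid genes Kel (5.61) and Tspo2 (5.39), and the neutrophil granule genes Mpo (5.49), Camp (5.40), Ngp (5.03) and Ltf (4.99). Decreases were the growth factor Mst1 (-3.84), Art2b (-3.37), Gvin1 (-3.13), Trim5 (-3.12), Trim12a (-3.10), Noxa1 (-2.84) and Khdc1a (-2.81); Art2b, Gvin1 and the Trim genes have close copies and are uncertain.

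Cell cycle genes had 0 of 30 members called over all genes and 26 adjusted over the list alone, all 30 higher (median log2 fold change 1.87; camera adjusted p 7.01e-11, or 0.582 with an estimated correlation). Antioxidant genes had 0 and 13 of 28 (0.58; 4.90e-05, 0.582). This list includes Hmox1, which macrophages express and which was at 30.2 and 792 CPM in young Treg and 2683 and 3065 in the labelled libraries. Effector Treg genes had 0 and 10 of 20 (1.09; 1.89e-05, 0.582), naive genes 0 and 2 of 15 (-0.90; 0.00245, 0.613) and ribosomal genes 0 and 48 of 62 lower (-0.60; 9.06e-17, 0.582). The senescence list (0 and 4 of 11; median 0.19) did not pass (camera adjusted p 0.601). The macrophage list (2.62; 1.13e-05, 0.582) and the erythroid list (3.69; 1.67e-04, 0.582) were higher as well, among 14 lists higher and 2 lower by camera and none with an estimated correlation. The cell cycle list averaged 4.05 and 4.89 log2 CPM in young Treg and 6.37 and 6.23 in the labelled libraries. The erythroid list went from 0.94 and 4.89 to 6.97 and 8.22. Higher cell cycle and effector Treg genes therefore cannot be separated from RNA of other cells.

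Tconv labelled Dcaf1-deficient were compared with young Tconv to ask the same of conventional cells. Rpl29 fell from 841 ± 6.55 to 40.4 ± 3.60 CPM (DESeq2 log2 fold change -4.38, DESeq2 adjusted p 4.25e-13) and Mst1 from 9.45 ± 0.163 to 0.169 ± 0.170 CPM (-5.80, DESeq2 adjusted p 5.47e-06). Trim12a, Trim5 and the mitochondrial ribosome gene Mrpl48 fell by 4.02, 3.60 and 3.45, while Trim34b rose by 3.86. Other increases were Col6a4 (6.52), Ngp (5.49), St6galnac2 (5.13), Ppfia4 (4.52), Ifitm1 (4.12) and St6galnac1 (3.78). Xist rose by 9.05 while the Y-linked genes Ddx3y, Kdm5d and Eif2s3y fell by 10.20, 9.74 and 9.69: both young Tconv libraries read as male and both labelled libraries as female, so sex and label coincide within this comparison. A sex term estimated over all 12 libraries, which assumes 1 sex effect in every group, gave 1 called gene in edgeR, against 0 without it.

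These genes were named by DESeq2 after the values were seen, since edgeR called 0 higher and 0 lower. In edgeR 954 genes had an unadjusted p under 0.05; DESeq2 called 152 higher and 75 lower, limma 0 and 1, and edgeR fitted to Tconv alone 9 and 7. Cell cycle genes had 0 of 30 members called and 20 adjusted over the list alone (median log2 fold change 1.99; camera adjusted p 3.23e-13, or 0.560 with an estimated correlation). Interferon genes had 0 and 9 of 30 (0.65; 2.67e-11, 0.442), effector Treg genes 0 and 9 of 20 (1.21; 1.83e-09, 0.442) and ribosomal genes 0 and 2 of 62 (-0.29; 2.31e-13, 0.560). The macrophage list (2.78; 3.45e-04, 0.560) and the erythroid list (4.45; 0.00444, 0.573) were higher as well. Higher cell cycle and effector Treg genes therefore cannot be separated here from RNA of other cells. By camera 15 lists were higher and 1 lower, and none with an estimated correlation.

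Treg labelled Dcaf1-deficient and aged Treg were compared with each other, since this contrast shares no control with the others. Foxp3 was lower in the labelled libraries (580 ± 63.7 against 1366 ± 877 CPM; log2 fold change -1.24, SE 0.52, edgeR adjusted p 0.635), with 746 CPM in aged Treg 1 and 1986 in aged Treg 2. Cdkn1a differed by 0.56 (SE 0.79) and Cdkn2a by 0.25 (SE 1.21), less than the spread of the aged libraries; Cdkn2a turned direction without aged Treg 2 or labelled Treg 1. Il2ra, Gstp1 and Dcaf1 (Vprbp) differed by -0.36, -0.13 and -0.19. No gene passed in edgeR, 702 had an unadjusted p under 0.05, DESeq2 called 1 higher and 63 lower and limma 0 and 0, but edgeR called 984 without aged Treg 1.

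Treg identity genes were lower in the labelled libraries (0 of 15 called, 5 adjusted over the list alone; median -1.24; camera adjusted p 1.17e-04, or 0.577 with an estimated correlation), as were effector Treg genes (0 and 8 of 20; -0.82; 0.00309, 0.577). Most of this came from aged Treg 2: mean log2 CPM in labelled and in aged Treg was 7.15 and 6.94 against 7.53 and 8.64 for identity, and 6.69 and 6.44 against 6.88 and 7.69 for effector genes. T cell genes as a whole were lower in the same way (7.87 and 7.78 against 8.03 and 8.84). Cell cycle genes were higher (0 and 0 of 30; 0.66; 4.79e-06, 0.577), but only against aged Treg 2: their mean log2 CPM was 6.37 and 6.23 in the labelled libraries and 6.25 and 4.75 in aged Treg. The macrophage list (1.25; 1.19e-04, 0.577) and the erythroid list (1.86; 3.05e-05, 0.577) moved the same way, so the cell cycle difference cannot be separated from RNA of other cells. By camera 12 lists were higher and 3 lower, and none with an estimated correlation.

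The overlap asks whether young cells labelled Dcaf1-deficient share expression changes with aged cells. In Treg, the genes ranked first by DESeq2 after the values were seen were higher for Rnpep (1.70 with age and 1.58 with the label), Acot11 (1.63 and 1.69), the p53 target Phlda3 (3.42 and 3.53), Cobl (5.51 and 4.73), Hmgb3 (0.80 and 0.91) and Gna15 (1.497 and 1.78). Lower were Ctse (-3.003 and -2.45), Ntn1 (-1.82 and -2.03), Cd40lg (-1.37 and -1.34), Rassf2 (-0.59 and -0.56), Ift80 (-1.86 and -1.96) and Eif3f (-0.46 and -0.49). In Tconv, Prr13 (1.12 and 1.11), the phosphatase gene Inppl1 (2.12 and 1.94), Acot7 (1.76 and 1.63), the costimulatory ligand gene Tnfsf4 (4.37 and 4.22), Cpd (1.65 and 1.88) and Tbc1d2 (1.88 and 2.83) were higher. Ctse (-3.01 and -3.29), Dusp2 (-1.34 and -1.11), Crebzf (-0.68 and -0.74), Rpl22 (-0.63 and -0.52), Wbscr27 (-1.80 and -0.84) and Gid4 (-0.60 and -0.45) were lower.

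In edgeR 0 genes were shared in either cell type, as each overlap includes a contrast with 0 calls. By DESeq2, Treg shared 181 genes higher and 181 lower, where independent lists give 26.5 and 18.5, and Tconv 72 and 32, where independent lists give 19.7 and 6.44. Across genes, which are not independent replicates, the fold changes of the Treg contrasts correlated at r 0.71. Simulated unchanged groups gave 0.51 (0.46 to 0.55 in 50 draws). The draws made every library anew, gene by gene, around the mean of the young libraries. They hold no difference that runs across many genes, such as that between young Treg 1 and 2 (macrophage list 2.87 and 7.27 log2 CPM). A value above their range therefore does not measure a shared effect of age and label. The covariance was 0.779 against 0.231 simulated, a difference of 0.549. Without young Treg 2 and aged Treg 1 r was 0.57 and the covariance 1.96. No draws were simulated for that smaller set of libraries, where fewer shared controls raise the correlation of unchanged groups. These values therefore cannot show whether any excess remains. In Tconv r was 0.29 against 0.50 simulated, and the covariance 0.447 against 0.246, a difference of 0.201. The 2 young libraries are too few to split, so part or all of these differences from the draws may come from the shared controls. All young libraries read as male, while aged Treg 2, labelled Treg 2, aged Tconv 2 and both labelled Tconv libraries read as female. The macrophage list averaged 8.43 and 5.27 log2 CPM in aged and 8.67 and 9.04 in labelled Treg, against 2.87 and 7.27 in young Treg. Sex and RNA of other cells may thus be part of both contrasts. They cannot be told apart here from changes shared by age and label. Aged Treg 1 also resembled the labelled Treg libraries in ways given in the closing section.

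Interactions tested whether age or the label acted differently in Treg and Tconv. Treg identity genes rose less with age in Treg than in Tconv (median difference -2.09 on the log2 scale; 0 of 15 called, 3 adjusted over the list alone; camera adjusted p 4.18e-06, or 0.924 with an estimated correlation), as did exhaustion genes (-2.72; 0 and 7 of 14; 1.03e-05, 0.924). For the label, antioxidant genes rose more in Treg (0.31; 0 and 0 of 28; 1.62e-05, 0.967) while Treg identity genes were lower in labelled Treg (median -0.91) and higher in labelled Tconv (0.30; difference -0.76; 0 and 0 of 15; 4.00e-04, 0.967). T cell genes as a whole fell more in Treg (8.95 and 8.42 to 7.87 and 7.78 log2 CPM) than in Tconv (9.13 and 9.04 to 8.97 and 8.95). The difference between the cell types therefore cannot be read as specific to identity genes, though in Tconv these rose while T cell genes fell. The macrophage list, which shares Hmox1 with the antioxidant list, rose from 2.87 and 7.27 to 8.67 and 9.04 in Treg. In Tconv it rose from 0.95 and 4.003 to 5.73 and 5.80, so the antioxidant difference cannot be separated from other cells. In edgeR 0 genes passed for age, with 615 at an unadjusted p under 0.05, 34 higher and 100 lower by DESeq2 and 0 and 1 by limma; without aged Tconv 1 edgeR called 112. For the label 0 passed, with 260 at an unadjusted p under 0.05, 1 higher and 0 lower by DESeq2 and 0 and 0 by limma.

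Genes near Dcaf1 were examined after Rpl29 and Mst1 had been seen. Within 10 Mb of Dcaf1, 10 of 170 tested genes changed the same way in both cell types in the labelled libraries at an unadjusted edgeR p under 0.01. Besides Rpl29 and Mst1, these included the hydrolase gene Abhd14b (log2 fold change -2.67 in Treg and -3.06 in Tconv), Tmie (-1.68 and -1.38), Parp3 (-1.50 and -0.85) and the NAD synthesis gene Nmnat3 (-0.92 and -0.96). Bsn (1.34 and 1.79), the exonuclease gene Trex1 (0.96 and 0.82) and Fbxl2 (2.06 and 2.67) were higher. None of the 10 passed in edgeR in either cell type (lowest adjusted p 0.131 in Treg and 0.127 in Tconv). Col6a4, named above by DESeq2 in both cell types, also lies within 10 Mb (chromosome 9, 105989454 to 106096783) but is not among the 10. By DESeq2, 29 of 1185 calls for the label in Treg and 19 of 227 in Tconv lay within 10 Mb. That stretch holds 170 of 9495 tested genes. In aged Treg 1, Rpl29 was at 92.7 CPM, against 438 in aged Treg 2 and 606 and 495 in aged Tconv.

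**Figure D4:**
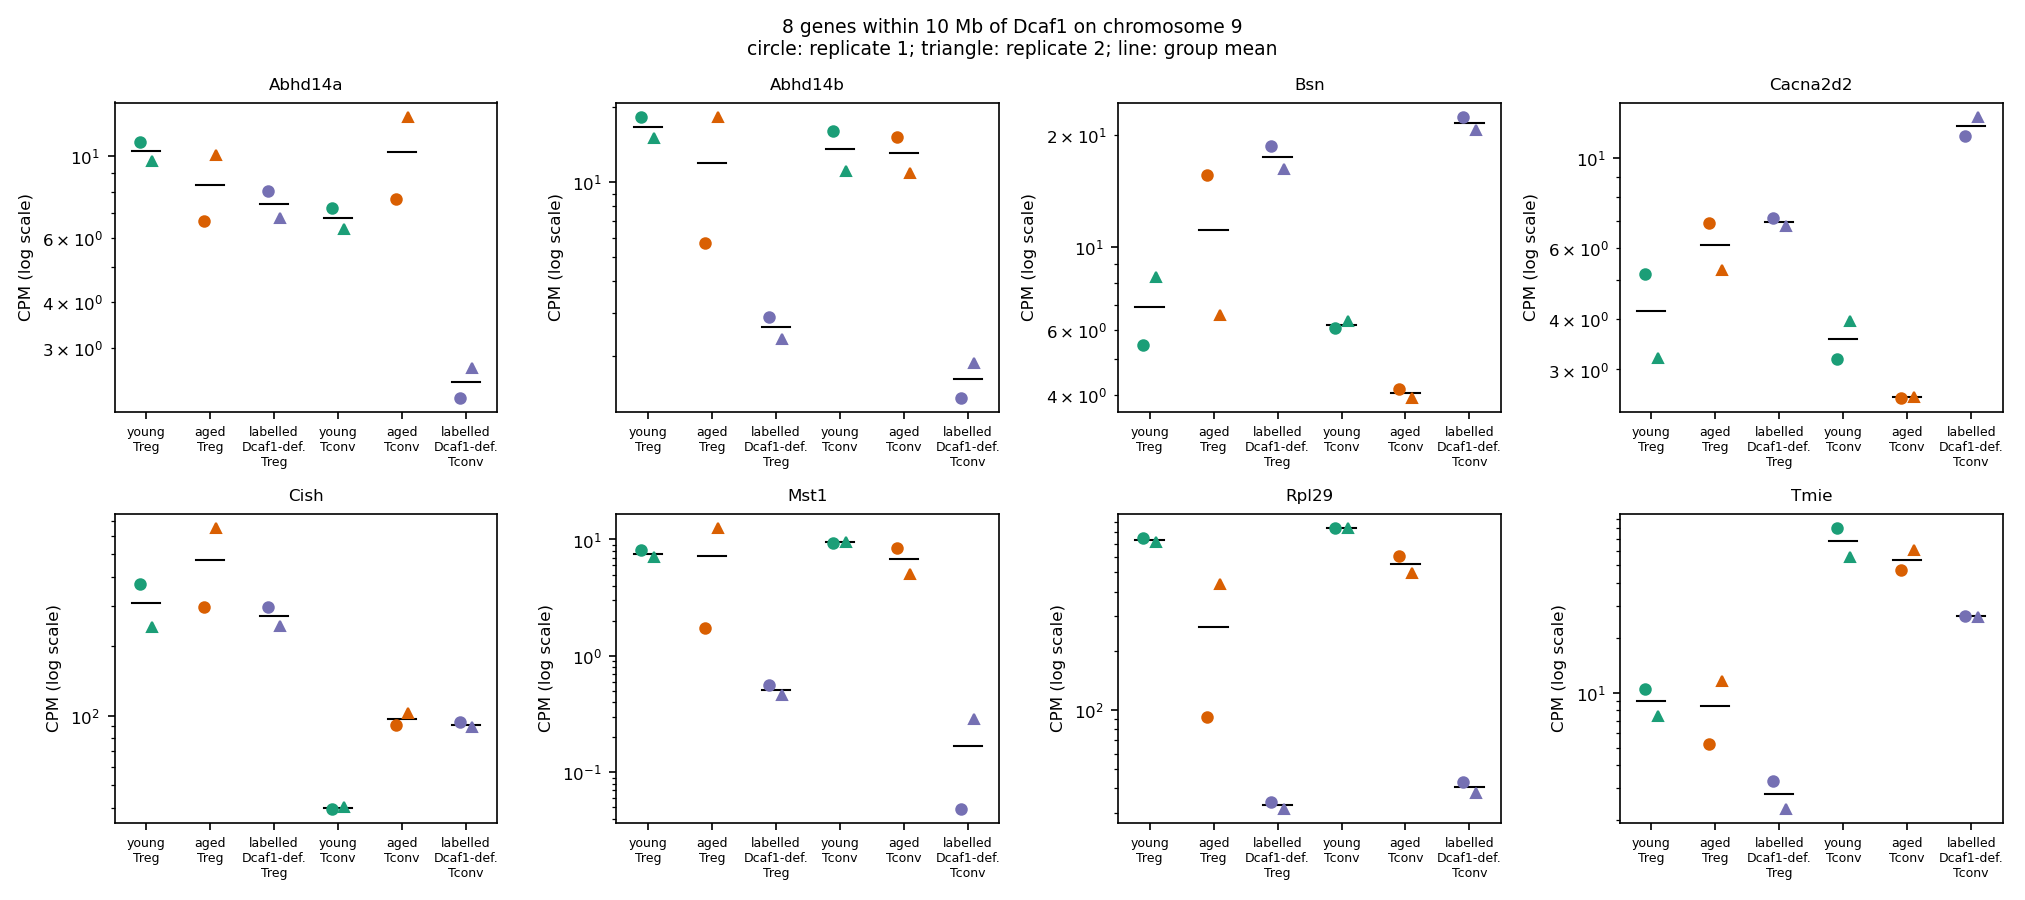
CPM (vertical axes, log scale) of 8 genes within 10 Mb of Dcaf1 that differed between labelled and young Tconv, in the 6 groups; circles are replicate 1, triangles replicate 2 and lines group means. Rpl29 is at 92.7 CPM in aged Treg 1 and at 438 in aged Treg 2.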

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

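The tests of the 3 patterns below were all chosen after the results were seen; the list tests of the interactions were planned. Their criteria were also written after those results, and where they were changed or departed from it is said below.

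Several effects differed between Treg and Tconv. For age, camera found lists that changed differently in the 2 cell types, with median differences (Treg minus Tconv, log2) of -2.09 for Treg identity, -2.72 for exhaustion, 0.38 for interferon response and -0.52 for glycolysis genes. For the label these were -0.76 for Treg identity, -0.55 for naive, 0.31 for antioxidant, -0.27 for interferon response and -0.26 for ribosomal protein genes. T cell genes as a whole also fell more in labelled Treg (8.95 and 8.42 to 7.87 and 7.78 log2 CPM) than in labelled Tconv (9.13 and 9.04 to 8.97 and 8.95), so the lower identity and naive genes cannot be read as specific. None of the 9 held with an estimated correlation, where the adjusted p was 0.924 for each age list and 0.967 for each label list.

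Single genes moved in opposite directions in every library of the 2 cell types, a difference picked by that rule and not tested. For age these were Noxa1 (-4.73), Il1rl2 (1.93), Cd200 (-1.27) and Plagl1 (-3.92). For the label they were Krt17 (-1.81), Ikzf2 (-1.35), Il4 (1.98), Gbp5 (-0.84), Gbp2b (-3.09), Bcam (-1.58) and Arhgap20 (-2.26), and the mean of the Treg identity genes (-0.93). The values are differences of mean log2 CPM changes, and the Gbp genes share sequence.

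The first pattern was the uneven level of macrophage, B cell and red cell transcripts in the Treg libraries. The values argue against age as the whole cause: on the macrophage list the lowest aged library lay below the highest young one (a difference of -1.996, SE 0.31 over 16 genes). RNA of other cells that came through the sort for CD4 and CD25 may explain part of it: young Treg 2 had less of 17 T cell genes than young Treg 1 (median difference -0.56, all 17 lower). In the labelled Treg 2 library C1qb reached 904 CPM and Hbb-bs 4122 CPM, and Hmox1 is both a macrophage and an antioxidant gene. Dcaf1 deficiency stays open: the labelled libraries lay at least 1.40 above the highest young one, but the young libraries differed by 4.40, so label and cell mixture cannot be told apart here. Sex was not tested as a cause.

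The second pattern was the likeness of aged Treg 1 to labelled Dcaf1-deficient Treg 1 (r 0.993 across genes, against 0.914 with aged Treg 2). Genes near Dcaf1 were chosen in Tconv alone, and their level was placed on a scale from young (0) to labelled (1) libraries. For aged Treg, 0 was the mean of both young Treg libraries, and for young Treg 2 it was young Treg 1 alone. Aged Tconv were placed between young and labelled Tconv. Positions and bounds below are thus compared across unlike scales. None of the explanations tested is excluded. A mislabelled or mixed library may explain the likeness: aged Treg 1 lay at a median of 0.825 over 9 genes (quartiles 0.780 and 0.914). RNA of other cells stays open: young Treg 2, which holds such RNA too, lay at 0.213 (quartiles 0.0384 and 0.338), but has as little as 0.267 of the level of aged Treg 1, so a position of 0.221 would be enough. That share is the lowest of 3 lists and comes from the erythroid list (4.89 against 6.79 log2 CPM). The macrophage list differed less (7.27 against 8.43), and the B cell list was higher in young Treg 2 (8.51 against 8.34). Their shares would set a higher bound, so this rests on the erythroid list. The 6 marker genes that fell in labelled Tconv changed by a median of -1.45 from young Treg 1 to aged Treg 1 (upper quartile -1.05), against -0.91 for 17 T cell genes (lower quartile -1.16), and these ranges overlap. Age has little in its favour, as aged Treg 2 lay at -0.0288 (upper quartile 0.229), aged Tconv 1 at 0.109 and aged Tconv 2 at 0.226. All 3 medians lie below the bound of 0.413, so the criterion as written, on medians, speaks against age. Age is left open all the same, a departure from that wording: the script also asked that the spread lie below the bound, the upper quartile of aged Tconv 2 is 0.432, and only 1 other aged Treg library exists. The first run had used 6 genes that also had to change in Treg, which the written criterion did not ask for, and had excluded age with its spread; that run is not used. Groups were kept as labelled.

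The third pattern was the change of genes near Dcaf1 in the labelled libraries. RNA of other cells is argued against for the 7 genes that fell, since it lowers a transcript at most by the share of the T cells: in labelled Tconv they changed by a median of -1.96 (upper quartile -1.15), against -0.10 for 17 T cell genes (lower quartile -0.28). The 7 genes were picked for falling, so the test lies in how little the T cell genes changed. For the 3 genes that rose it stays open: they changed by a median of 0.31 from young Treg 1 to young Treg 2, against 1.34 in labelled Treg, which is too few genes to decide. These tests replaced a comparison with young Treg 2 alone, here and in the pattern above, which had argued against such RNA in both but took no account of its smaller amount there. A chromosome segment carried with an engineered allele may explain it, and so may downstream changes of Dcaf1 loss. The criterion written first asked for a share near Dcaf1 above every other window of 20 Mb. Near Dcaf1 5.88% of 170 genes changed in both cell types against 0.954% elsewhere (one-sided Fisher's exact test, adjusted p 7.48e-04 over 73 windows), but chromosome 7 from 100000000 to 120000000 held 6.67% of 90 genes (adjusted p 0.0124), among them Trim5, Trim12a, Trim34b and Mrpl48. Read to the letter, this speaks against the segment, and the share near Dcaf1 lies within the range of the other windows, as written for downstream changes. That criterion also asked for changes spread over the genome. Of the 99 genes changed in both cell types, 10 lay near Dcaf1 and 6 in the chromosome 7 window, and the others lay outside both. Outside both windows the lowest unadjusted one-sided Fisher's exact p was 0.0824, as for changes spread over the genome. Such a spread does not account for the higher shares of both windows, so the values do not decide for downstream changes either. Since the shares of both windows could not be distinguished (Fisher's exact test, two-sided p 0.792), a comparison added after the result, both explanations are left open. A looser rule, which asked only for the exact test near Dcaf1, was tried after this result and would have favoured the segment; it is not used.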

How the results depend on the processing

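The sex term, the macrophage and B cell terms and the fit without young Treg 2 and aged Treg 1 were chosen after the data were seen; the other alternatives were fixed beforehand. RLE size factors, no low-count filter and a log2 fold change of at least 1 left each total of called genes within 1.5 times its first value, though the fold limit took the genes lower with age in Tconv from 235 to 76. Unless stated, the cause of a change was not tested.

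DESeq2 called 722 genes for age in Treg, 1185 for the label in Treg, 2043 for age in Tconv, 227 for the label in Tconv, 663 between the young cell types, 134 and 1 for the age and label interactions and 64 between labelled and aged Treg, where edgeR called 0, 0, 841, 0, 76, 0, 0 and 0. Its overlaps were 362 genes in Treg and 104 in Tconv, against 0. In simulated data DESeq2 called 45 to 65 unchanged genes in the comparisons given here where edgeR called 1 to 11. limma on the deposited log2 values called 2 for age in Treg, 1 for the label in Tconv, 166 between cell types and 1 for the age interaction, with 1 shared gene in Tconv. Tconv alone gave 16 genes for the label and 6 shared genes, and the young groups alone 2, with fewer libraries to estimate the spread.

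With the replicate block 40 genes were called between the young cell types, 29 higher and 11 lower; no other count of calls moved by over 1.5 times. Nothing in the labels pairs equal numbers, and of 15 pairs of groups 4 had deviations correlated above 0.1. The lowest was -0.656, young with aged Treg, and the highest 0.677, young Treg with young Tconv. Aged Treg with aged Tconv gave 0.271 and labelled Treg with labelled Tconv 0.0414. The numbers were not taken as pairs in the first fit, which treats all libraries as independent. Labelled Treg 1 read as male (Xist at 1.37 CPM) and labelled Tconv 1 as female (Xist at 1321 CPM), so they did not come from the same mouse. For the other numbers a mouse shared by Treg and Tconv is not excluded. A preparation shared by Treg and Tconv is not excluded for any number. The tag term gave 437 genes for age in Tconv, 167 between cell types and 46 for the age interaction.

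The sex term gave 1 gene for age in Treg, 2 for the label in Treg, 303 for age in Tconv, 1 for the label in Tconv, 2 for the age interaction and 1 shared gene in each cell type. The macrophage and B cell terms gave 1 gene for the label in Treg, 1 for the label in Tconv and 1 between cell types. Without young Treg 2 and aged Treg 1 the counts were 244 for age in Treg, 2219 for the label in Treg, 1431 for age in Tconv, 38 for the label in Tconv, 215 between cell types, 10 for the label interaction and 1693 between labelled and aged Treg, with 114 and 17 shared genes. That fit rests on 1 young and 1 aged Treg library, each assumed to vary like the other groups, and its libraries were chosen from the values, so its calls are no independent evidence.

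Leaving out 1 library at a time gave 0 to 434 genes for age in Treg (highest without aged Treg 1), 0 to 15 for the label in Treg (without young Treg 2), 0 to 2340 for age in Tconv (0 without either young Tconv library, 93 without aged Tconv 2, highest without aged Tconv 1) and 0 to 21 between cell types. It gave 0 to 112 for the age interaction (without aged Tconv 1), 0 to 984 between labelled and aged Treg (without aged Treg 1), and 0 to 12 and 0 to 2 shared genes in Treg and Tconv. The lone library left was assumed to vary like the other groups. The label contrast in Tconv and the label interaction had 0 throughout, with 954 and 260 genes at an unadjusted p under 0.05 in the full fit and 227 and 1 by DESeq2.

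The lists passing camera with an estimated correlation were 0 in all 8 comparisons. With fry they were 3, 1, 5, 1 and 2 for age in Treg, the label in Treg, age in Tconv, the label in Tconv and the cell types, and 0 in the other 3. With the tag term 9 lists passed between labelled and aged Treg, and without the 2 libraries 5 between cell types and 13 for the label interaction.

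Foxp3 between aged and young Treg, 0.29 in the first fit, reversed to -0.64 with the tag term, -0.21 with the sex term and -1.21 with the macrophage and B cell terms, and ran from -0.59 without aged Treg 2 to 0.83 without aged Treg 1. Gstp1 in labelled against young Treg reversed to -0.0380, -0.0596 and -0.0103 with the sex term, with the macrophage and B cell terms and without both libraries, and ran from -0.0179 without young Treg 2 to 0.0629 without young Treg 1. Between labelled and aged Treg the macrophage and B cell terms reversed Cdkn1a to -0.16 and Cdkn2a to -0.94, and Cdkn2a ran from -0.25 without aged Treg 2 to 1.02 without aged Treg 1. Dcaf1 (Vprbp) between the young cell types reversed to 0.00266 without both libraries. None of these reversed values was called in edgeR. Of 1554 values of named genes under the alternatives, 1067 kept direction and side of the threshold, 462 lost the threshold, 11 gained it and 14 reversed.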

Other observations

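Xist and 4 Y-linked genes gave the sex of each mouse. Xist was between 1263 and 2018 CPM in aged Treg 2, labelled Dcaf1-deficient Treg 2, aged Tconv 2 and both labelled Tconv libraries, where the Y-linked mean was at most 0.2204 CPM. In the other 7 libraries Xist was at most 2.94 CPM and the Y-linked mean at least 119 CPM. The 4 young wild-type libraries were all of the second kind.

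Genes of the exocrine pancreas were present in some spleen libraries. Amy2a5 was at 252 CPM in young Treg 2 and 146 in labelled Dcaf1-deficient Treg 2, at 4.997 in aged Treg 1 and 5.87 in labelled Treg 1, and at 0 in young Treg 1 and aged Treg 2. In Tconv it was at 15.2 CPM in young Tconv 2, at 19.2 and 23.7 in the labelled libraries and at 0 in the other 3.

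The labelled Tconv libraries were the closest pair of a group, with r 0.992 across genes and a chi-square of 5.71 per degree of freedom against counting noise, and were counted as 2 samples. Ctse was between 456 and 621 CPM in the 4 young wild-type libraries and between 51.6 and 104 in the other 8.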
